A study of Homo sapiens with 8 samples.

How the data were processed

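RNA sequencing measured gene expression in SH-SY5Y cells, an established human neuroblastoma line that the labels describe as neuronal progenitors. Per the labels' protocols, cells at 80% confluence received 0.5 ul of an adenovirus and RNA was isolated 48 h later. The virus carried BioID, a biotin ligase used for proximity labelling, fused either to Flag-tagged ERRg (estrogen-related receptor gamma, encoded by ESRRG) or to green fluorescent protein with a nuclear localisation signal (GFP). The groups are called ERRg and GFP, with 4 libraries each. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries.

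The authors deposited raw read counts per gene in a single table, with no normalisation. Per the submitters' processing notes, CASAVA, Trim Galore 0.6.6, STAR 2.7.8a, HTSeq 0.11.3 and DESeq2 were used with the genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited counts covered 67060 genes and 5 summary lines that name no gene. These were left out of library sizes and tests. They held reads outside annotated exons (20.9% ± 3.58 of all reads in GFP and 46.7% ± 1.31 in ERRg, SD, n = 4 each), reads in more than one gene (12.1% ± 1.46 and 5.44% ± 0.415) and reads aligned more than once (11.9% ± 1.32 and 6.41% ± 0.449). The lines for low alignment quality and for unaligned reads held 0 reads in each library. Reads assigned to genes ranged from 21.02 to 23.0 M per library in ERRg and from 27.7 to 35.5 M in GFP, so a gene at 1 CPM (counts per M reads) of the library's gene reads rested on at least 21.02 reads. Gene symbols came from a name table (60463 identifiers matched). Positions, gene types, GC content, transcript length and span came from GENCODE release 29 on GRCh38, which holds 58488 of the identifiers. GC content and length are those of the longest annotated transcript of a gene, which need not be the one these cells mainly make. Some genes that most cells use, such as TUBB and FLOT1, are listed at 0 in all 8 libraries, so a 0 in the table was not read as absence of the RNA.

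The strand was checked from the counts. Over 250 antisense or other non-coding genes that overlap coding exons by at least 200 bases, the median count density was 2.54% to 3.55% of the opposite-strand density in GFP libraries and 4.60% to 6.005% in ERRg libraries. Reads shared with near-identical copies are uncertain for histones, ribosomal proteins and their pseudogenes, and for SNORD3A and MIR3648-1.

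Genes were compared with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with group as the sole term. The filter left 21993 of the 41858 genes with a count. CPM values are scaled to TMM effective library sizes and are given as mean ± SD with n = 4 per group. Log2 fold changes are ERRg over GFP with their standard error (SE). In all, 38 gene lists (6 primary and 32 secondary) were fixed before the data were examined, as were the tests and the first set of alternatives below. ESRRG was left out of each list. Lists were compared with other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists, and again with an estimated correlation. Library shares were compared by exact two-sided permutation tests over the 70 arrangements, for which the smallest p is 0.0286, adjusted over 12 measures. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The chi-square of counts per gene between libraries of a group ranged from 2.90 to 40.2, and no pair of libraries was a duplicate. Within ERRg it was 2.90 between replicates 1 and 2 and 5.03 between replicates 3 and 4, against 10.0 to 22.6 across these pairs. The 4 ERRg libraries may therefore not be equally independent.

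Named genes followed a fixed rule. ESRRG, ESRRA, ESRRB, PPARGC1A and PPARGC1B were always named. The 8 largest fold changes in each direction, ESRRG not counted, were named among genes with an adjusted p under 0.05, an average log2 CPM of at least 1, no overlap between the groups' libraries, and a symbol that is not a clone, long intergenic or pseudogene name. The 4 members with the smallest p in each primary list and the 2 in each secondary list could also be named. Genes named outside this rule are said to be so, and some that it names are not reported here.

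Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, other low-count filters, tests without mitochondrially encoded genes or without ESRRG, coding genes alone, the replicate number as a block, each library left out in turn, a test against a log2 fold change of 1, an adjusted p under 0.01, an estimated correlation and fry. Alternatives chosen after seeing the data were library totals, equal depth, the share of reads outside annotated exons as a covariate, and offsets. The offsets were smooth trends of log2 CPM on GC content alone or on GC content, transcript length and gene span, fitted per library to coding genes above a log2 CPM of 1 with mgcv 1.9.3 and passed to edgeR. They remove any part of the group difference that follows these properties, whatever its origin.

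The edgeR step was tested on simulated counts for ERRg against GFP. Of 100 genes changed by 1 on the log2 scale, 99 were recovered, and of 100 changed by 2, 100 were recovered, and 9 other genes of the 21498 tested were called, 4.33% of all calls. When a GC trend was added to the simulated ERRg libraries, 98.3% of the calls with TMM alone were false, against 4.78% of the calls with the offsets over GC content, length and span, which tested 13301 coding genes. The added trend was linear in the same annotated GC content that the offsets use, with no trend over length or span. The offsets were therefore bound to remove it, and 4.78% is no estimate of false calls in the real data.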

Results

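Gene expression was measured by RNA sequencing in 8 libraries of SH-SY5Y cells, 4 that had received BioID-ERRg adenovirus and 4 that had received BioID-GFP adenovirus for 48 h. Reads assigned to genes numbered 31.5 ± 3.22 M in GFP (SD, n = 4, range 27.7 to 35.5) and 21.8 ± 0.869 M in ERRg (SD, n = 4, range 21.02 to 23.0). The single comparison in the design asks how expression of BioID-ERRg changes the transcriptome of these cells.

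ESRRG, the orphan nuclear receptor delivered by the virus, was 23.2-fold higher in ERRg libraries. Its level was 808 ± 73.2 CPM in ERRg and 34.9 ± 2.34 CPM in GFP (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest this design allows). All 4 ERRg libraries, from 711 to 888 CPM, lay above all 4 GFP libraries, from 32.7 to 37.1 CPM. The gene (ENSG00000196482.18) lies on chromosome 1 from 216503246 to 217137755 on GRCh38, and these counts do not separate reads of the virus from reads of the cells' own gene. Its log2 fold change was 4.53 (SE 0.11, edgeR adjusted p = 1.87e-17).

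**Figure D1:**
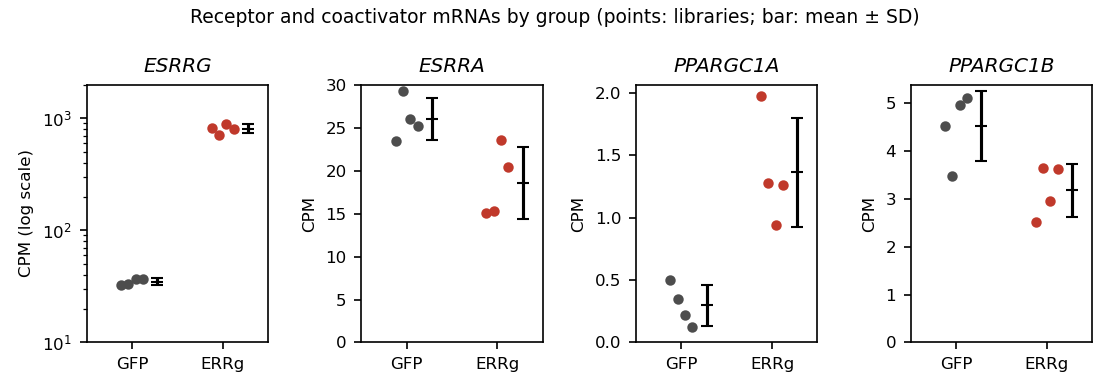
CPM of ESRRG (log axis) and of ESRRA, PPARGC1A and PPARGC1B (linear axes) in each library, with the mean ± SD of 4 libraries beside the points. ESRRG in the 4 ERRg libraries sits between 711 and 888 CPM, above the 4 GFP libraries at 32.7 to 37.1 CPM.

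The secreted phosphoprotein SPP1 (osteopontin), the endocytic receptor LRP2 (megalin), the calcitonin receptor CALCR, the calcium-binding protein CABP7 and the nuclear long non-coding RNA NEAT1 were among the genes that rose most besides ESRRG. SPP1 rose from 6.17 ± 0.564 to 139 ± 9.62 CPM (log2 fold change 4.49, SE 0.11). LRP2 rose from 0.0764 ± 0.0676 to 4.47 ± 0.8289 CPM (5.84, SE 0.35) and CALCR from 0.122 ± 0.0869 to 4.85 ± 0.657 CPM (5.29, SE 0.32). CABP7 rose by 4.09 (SE 0.21), NEAT1 by 4.07 (SE 0.14), ZFYVE28 by 3.36 (SE 0.16), LRTM1 by 3.35 (SE 0.22) and the retinoid isomerase RPE65 by 3.31 (SE 0.17) on the log2 scale. The genes that fell most included the imprinted, retrotransposon-derived gene RTL1, the chemokine receptor CXCR4, the synaptotagmin SYT9 and the neurotrophin receptor NGFR. RTL1 fell from 28.6 ± 5.76 to 1.08 ± 0.404 CPM (log2 fold change -4.73, SE 0.19), SYT9 from 14.3 ± 1.56 to 0.972 ± 0.274 CPM (-3.88, SE 0.17) and CXCR4 from 7.23 ± 0.299 to 0.525 ± 0.174 CPM (-3.76, SE 0.20). NGFR had a log2 fold change of -3.55 (SE 0.27), the natriuretic peptide receptor NPR1 of -3.48 (SE 0.29) and the prostaglandin receptor PTGER1 of -3.43 (SE 0.25). With the offsets PTGER1 was at -1.72 and NGFR at -2.37. The small RNA genes MIR3648-1 and SNORD3A, which have near-identical copies, had log2 fold changes of -4.12 (SE 0.30) and -4.11 (SE 0.33). In these 16 genes the edgeR adjusted p was at most 1.09e-09, and no ERRg library overlapped a GFP library, as the rule for naming them required. SPP1 lies on chromosome 4 from 87975650 to 87983426, LRP2 on chromosome 2 from 169127109 to 169362685, CALCR on chromosome 7 from 93424487 to 93574730, RTL1 on chromosome 14 from 100879753 to 100903722 and CXCR4 on chromosome 2 from 136114349 to 136118165.

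**Figure D2:**
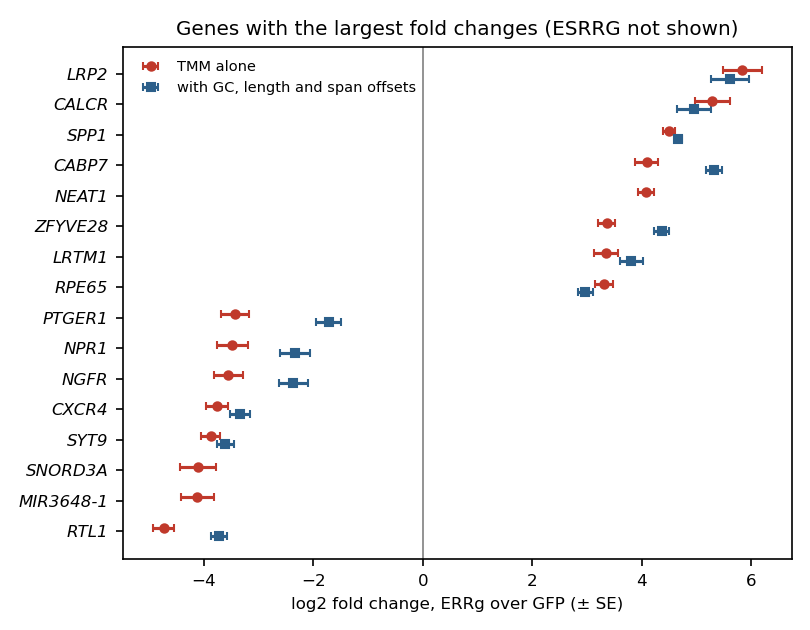
Log2 fold change (ERRg over GFP, bars: SE, n = 4 per group) of the 8 genes that rose most, ESRRG left out, and the 8 that fell most by the naming rule, with TMM alone (circles) and with offsets for GC content, length and span (squares, coding genes alone). Each of the 13 coding genes keeps its direction with the offsets, from 5.61 for LRP2 to -3.73 for RTL1.

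Of 21993 genes tested, 8529 were higher and 7899 lower in ERRg by edgeR at an adjusted p under 0.05, which is 74.7% of the genes. With upper-quartile factors 11041 were higher and 6045 lower, and with library totals 11791 were higher and 5383 lower. The median log2 fold change of all genes was 0.09 with TMM, 0.40 with upper-quartile factors and 0.50 with library totals. Against a log2 fold change of 1, 1692 genes were higher and 2302 lower. With the share of reads outside annotated exons as a covariate, which separates the groups without overlap, 6 genes were higher (ESRRG, SPP1, ZFYVE28, LMCD1, NPTX2 and COL14A1) and 2 lower (AC006042.3 and BX005019.1). LMCD1, NPTX2, COL14A1 and the lower pair were named after their values were seen. AC006042.3 was called higher without the covariate (1.40) and BX005019.1 was not called (0.54). All 8 values come from a fit that leaves the groups little variation of their own.

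The composition of the libraries differed between the groups beyond the spread of replicates. Reads outside annotated exons made up 46.7% ± 1.31 of all reads in ERRg and 20.9% ± 3.58 in GFP. Among reads assigned to genes, NEAT1 and MALAT1, which are retained in the nucleus, held 2.68% ± 0.388 in ERRg and 0.481% ± 0.0995 in GFP. Mitochondrially encoded genes held 7.72% ± 0.540 and 3.98% ± 1.19. Cytosolic ribosomal protein genes held 3.34% ± 0.305 and 6.35% ± 0.411, histone genes 0.308% ± 0.0528 and 0.908% ± 0.152, and the signal recognition particle RNA RN7SL1 0.382% ± 0.128 and 2.16% ± 0.799 (SD, n = 4 each). Each of these shares had an exact permutation p = 0.0286 (adjusted p = 0.0343 over 12 measures), with no overlap between groups. The 10 most abundant genes held 8.79% ± 0.2497 in ERRg and 7.58% ± 1.00 in GFP, a difference that did not pass the test (exact permutation p = 0.0857, adjusted p = 0.0935) and that turned from 1.21 to -0.535 points without mitochondrially encoded genes in the denominator.

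**Figure D3:**
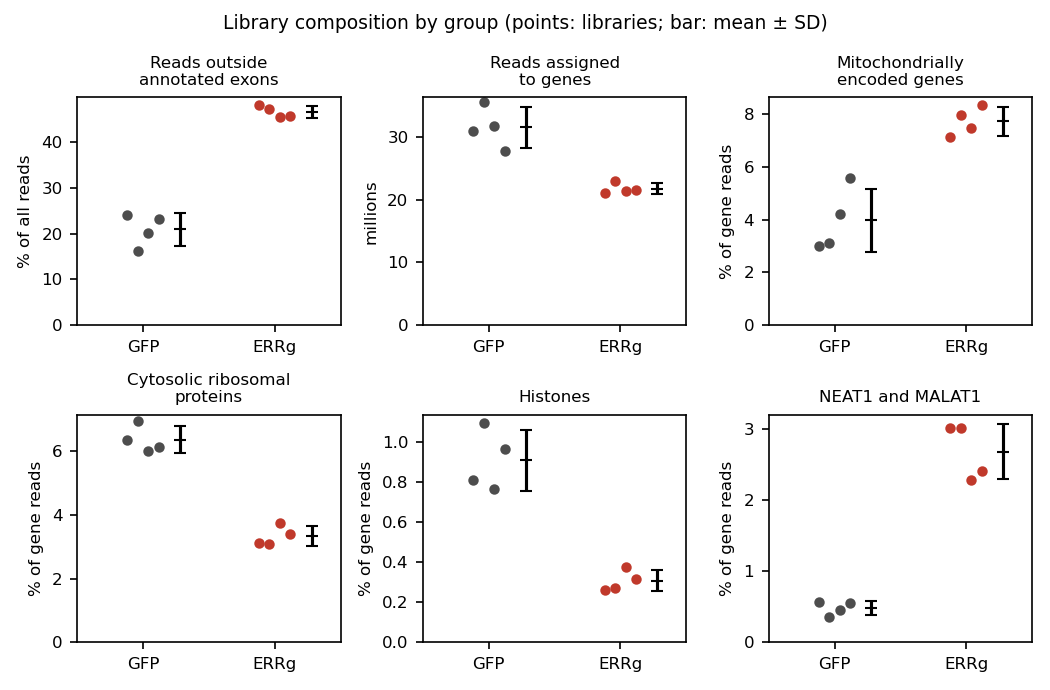
Library composition in each of the 4 GFP and 4 ERRg libraries, as percent of all reads, M reads or percent of gene reads, with the mean ± SD beside the points. Reads outside annotated exons range from 45.5% to 48.3% in ERRg and from 16.2% to 24.2% in GFP.

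Fold changes of coding genes followed the GC content of their transcripts. In the decile of coding genes with the lowest GC content (30.2% to 38.2%) the median log2 fold change was 0.63, and in the decile with the highest (61.2% to 74.5%) it was -1.39. GC content accounted for 52.6% of the variance of the log2 fold change across 11708 coding genes, transcript length for 14.2%, gene span for 20.8% and the 3 together for 57.8%. Genes are not independent replicates, so these shares carry no p-value. With offsets for GC content, length and span, edgeR found 4652 genes higher and 4861 lower of 13426 coding genes. Of the genes called in both fits, 2679 were higher in both, 3854 were lower in both and 1211 had opposite directions. The counts of each gene list of coding genes are therefore given with TMM alone and with these offsets.

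**Figure D4:**
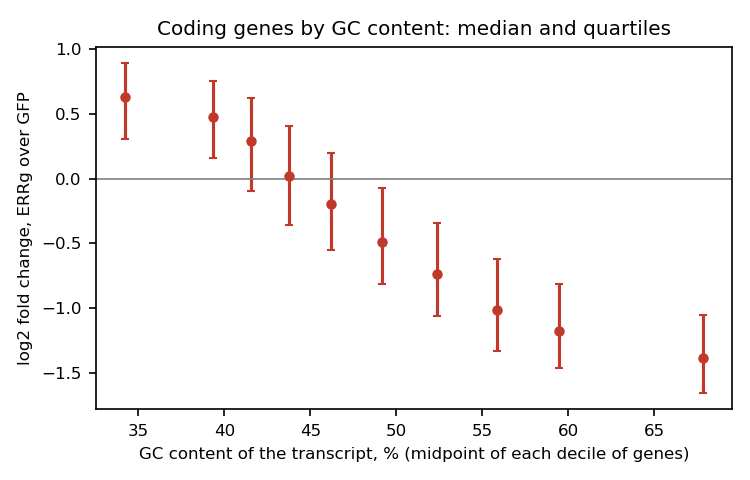
Median log2 fold change (ERRg over GFP) of coding genes by decile of GC content, each decile holding 1170 or 1171 genes. Bars show the quartiles, and the medians run from 0.63 at the lowest GC content to -1.39 at the highest.

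Among the receptor's relatives and coactivators, PPARGC1A, which encodes the coactivator PGC-1alpha, rose from 0.296 ± 0.163 to 1.36 ± 0.435 CPM (log2 fold change 2.16, SE 0.36, edgeR adjusted p = 1.56e-05). It rested on 3 to 14 reads per GFP library and 23 to 48 per ERRg library. ESRRA, the alpha receptor, fell from 26.1 ± 2.43 to 18.6 ± 4.17 CPM (-0.49, SE 0.13, edgeR adjusted p = 0.00192). Its direction turned with the offsets (0.85, SE 0.07, edgeR adjusted p = 7.80e-09), and it did not pass the test with upper-quartile factors (adjusted p = 0.169). PPARGC1B fell from 4.52 ± 0.733 to 3.18 ± 0.550 CPM (-0.50, SE 0.17, edgeR adjusted p = 0.0115), and its call ended with the offsets (-0.30, adjusted p = 0.0930). ESRRB had at most 9 reads in any library and was not tested. In the list of 17 receptors, coactivators and regulators of mitochondrial biogenesis, 5 were higher and 7 lower, with no shift as a set (median 0.01, camera adjusted p = 0.786). With the offsets 7 were higher and 0 lower (median 0.01, camera adjusted p = 0.283). PPRC1 fell by 0.91 and PPARD by 0.93 with TMM alone, and neither passed the test with the offsets (adjusted p = 0.635 and 0.407).

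Genes widely described as targets of estrogen-related receptors moved in both directions. Of 18 tested, 7 were higher and 8 lower, and the list did not differ from other genes (median 0.15, camera adjusted p = 0.820). The kinase PDK4, which inhibits pyruvate dehydrogenase, rose from 0.875 ± 0.296 to 4.91 ± 1.01 CPM (log2 fold change 2.47, SE 0.23). The sarcomeric mitochondrial creatine kinase CKMT2 rose by 1.496 (SE 0.15) and the medium-chain acyl-CoA dehydrogenase ACADM by 1.48 (SE 0.10). PDK2 fell by 1.47 (SE 0.14) and the cytochrome oxidase subunit COX8A by 2.18 (SE 0.14). With the offsets, 14 of the 18 were higher and 4 lower, PDK2 (-0.38) and COX8A (-0.26) among the lower, and the list was higher than other coding genes (median 0.52, camera adjusted p = 2.07e-04). That call was lost with an estimated correlation (adjusted p = 0.164). In the list of 11 genes described as dependent on PGC-1alpha in neurons, 3 were higher and 6 lower (median -0.48, camera adjusted p = 0.774). With the offsets 7 were higher and 3 lower (median 0.40, camera adjusted p = 0.177). NCEH1 was higher in both fits (0.73 and 0.40) and ATP5F1A was lower in both (-0.55 and -0.37).

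mRNAs of the respiratory chain moved apart by genome. Of the 13 mRNAs encoded by the mitochondrial genome, 10 were higher and 1 lower in ERRg (median log2 fold change 0.92, camera adjusted p = 0.0214, and adjusted p = 0.573 with an estimated correlation). That list was not called with the DESeq2 Wald test (median 0.89, camera adjusted p = 0.0700). MT-ATP8 rose from 279 ± 99.8 to 829 ± 83.5 CPM and MT-ND6 from 422 ± 166 to 1136 ± 94.4 CPM. Of 76 nuclear-encoded subunits of the respiratory complexes and ATP synthase, 62 were lower and 6 higher (median -0.88, camera adjusted p = 2.64e-08, and adjusted p = 0.451 with an estimated correlation). ATP5MC2 fell from 272 ± 42.4 to 90.5 ± 12.3 CPM, UQCRQ from 126 ± 23.8 to 42.7 ± 3.82 CPM and NDUFB11 from 98.9 ± 17.7 to 28.8 ± 5.44 CPM. With the offsets these 3 were lower by less (-1.14, -0.62 and -0.32). With the offsets 12 of the 13 mitochondrially encoded mRNAs were higher (median 1.30, camera adjusted p = 8.49e-05, and adjusted p = 0.611 with an estimated correlation), while the list was not called with an offset for GC content alone (median 0.97, camera adjusted p = 0.0859). The nuclear subunits did not then differ from other genes (22 higher, 33 lower, median -0.05, camera adjusted p = 0.417), while with the offset for GC content alone 50 were lower and 10 higher (median -0.42, camera adjusted p = 8.80e-05). With the share of reads outside annotated exons as a covariate, the nuclear list turned and was called higher (median 0.20, camera adjusted p = 0.0133), and the mitochondrially encoded list was not called (median -0.0083, camera adjusted p = 0.156). The mitochondrial share of gene reads was 7.72% in ERRg and 3.98% in GFP.

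Enzymes of mitochondrial fuel oxidation changed in both directions. In the tricarboxylic acid cycle, 6 of 19 genes were higher and 10 lower (median -0.39, camera adjusted p = 0.368). The dehydrogenase subunit DLD rose from 68.8 ± 3.93 to 149.5 ± 18.3 CPM, and IDH2 and MDH2 fell by 1.39 (SE 0.11) and 1.37 (SE 0.11) on the log2 scale. With the offsets 12 were higher and 6 lower (median 0.17, camera adjusted p = 0.314). IDH3G turned from -1.04 to 0.35, and IDH2 (-0.45), MDH2 (-0.59) and DLD (0.72) changed by less. In fatty acid beta-oxidation, 3 of 23 genes were higher and 17 lower (median -0.50, camera adjusted p = 0.125), and with the offsets 9 were higher and 7 lower (median 0.09, camera adjusted p = 0.317). ACADM and the electron-transfer flavoprotein dehydrogenase ETFDH were higher in both fits (ETFDH 1.18 and 1.20). HSD17B10 and ECHS1 were lower with TMM alone (-1.38 and -1.23) and did not pass the test with the offsets (adjusted p = 0.574 and 0.0939). Mitochondrial fusion, fission, import and quality control genes gave 6 higher and 15 lower of 29 (median -0.49, camera adjusted p = 0.117), and with the offsets 11 higher and 12 lower (median -0.03, camera adjusted p = 0.773, direction higher). CLPP (-1.73 and -0.21) and TIMM50 (-1.44 and -0.59) were lower in both fits. Mitochondrial ribosomal protein genes were lower (52 of 72, median -0.68, camera adjusted p = 1.14e-06, and adjusted p = 0.347 with an estimated correlation), a call that ended with the offsets (20 higher, 30 lower, median -0.04, camera adjusted p = 0.363). Of 10 oxidative muscle and heart genes, 4 were higher, CKMT2 among them, and 5 lower, TNNT1 among them (median -0.06, mean 0.04, camera adjusted p = 0.853, direction higher). With the offsets 5 were higher and 3 lower (median 0.31, camera adjusted p = 0.464), and TNNT1 went from -1.47 to -0.20.

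Several neuronal genes fell. The growth-cone protein GAP43 fell from 84.1 ± 11.5 to 20.7 ± 2.05 CPM and STMN3 from 53.2 ± 6.002 to 13.5 ± 2.04 CPM, and both stayed lower with the offsets (-1.70 and -0.69). Of 16 neuronal cytoskeleton and growth-cone genes, 2 were higher and 9 lower (median -0.39, camera adjusted p = 0.0292, and adjusted p = 0.521 with an estimated correlation). With the offsets 6 were higher and 9 lower (median -0.20, camera adjusted p = 0.283). Of 34 synaptic vesicle and exocytosis genes, 9 were higher and 21 lower (median -0.56, camera adjusted p = 0.186). With the offsets 13 were higher and 11 lower (median -0.03, camera adjusted p = 0.407, direction higher). Synapsin SYN2 was higher in both fits (1.47 and 1.81), while RPH3A (-1.27 and -1.01), SYT11 (-1.16 and -0.92) and STX1A (-1.37 and -0.18) were lower in both. Ion channel subunits gave 6 higher and 18 lower of 29 (median -0.55, camera adjusted p = 0.0846), and with the offsets 10 higher and 14 lower (median -0.25, camera adjusted p = 0.511). CACNA2D2 was lower in both fits (-1.76 and -0.998).

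Of 18 genes of noradrenergic identity, 14 were lower and 0 higher (median -0.77, camera adjusted p = 3.82e-04, and adjusted p = 0.449 with an estimated correlation). Dopamine beta-hydroxylase DBH, which makes noradrenaline, fell from 14.3 ± 2.08 to 3.03 ± 0.659 CPM and the noradrenaline transporter SLC6A2 from 79.8 ± 4.42 to 30.1 ± 4.88 CPM. Both were lower with the offsets (-1.14 and -0.73), while the list was not (7 higher, 7 lower, median 0.04, camera adjusted p = 0.956). Of 22 genes of the mesenchymal state, 16 were lower and 2 higher (median -0.66, camera adjusted p = 2.09e-05, and adjusted p = 0.347 with an estimated correlation). IGFBP3 fell from 86.0 ± 6.48 to 15.8 ± 1.16 CPM. With the offsets 14 were lower and 6 higher (median -0.44, camera adjusted p = 2.84e-04, and adjusted p = 0.476 with an estimated correlation). Fibroblast markers, several of which neuroblastoma cells also express, were lower in 10 of 11 genes (median -1.32, camera adjusted p = 2.09e-05, and adjusted p = 0.347 with an estimated correlation), and again in 10 of 11 with the offsets (median -0.48, camera adjusted p = 8.49e-05, and adjusted p = 0.254 with an estimated correlation). PDGFRB fell by 1.71 (SE 0.11) and COL5A1 by 1.61 (SE 0.10), and with the offsets by 0.86 and 0.89.

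Cytosolic ribosomal protein genes and replication-dependent histone genes were lower in both fits. Ribosomal protein genes were lower in 71 of 73 (median -1.29, camera adjusted p = 1.79e-27, and adjusted p = 0.347 with an estimated correlation), and in 59 of 73 with the offsets (median -0.58, camera adjusted p = 3.75e-13, and adjusted p = 0.531 with an estimated correlation). RPS14 fell from 1211 ± 193 to 319 ± 49.8 CPM. Histone genes were lower in 56 of 58 (median -1.97, camera adjusted p = 3.92e-28, and adjusted p = 0.347 with an estimated correlation), and in 43 of 56 with the offsets (median -0.69, camera adjusted p = 4.07e-11, and adjusted p = 0.531 with an estimated correlation). H2BC15 fell by 1.997 (SE 0.12) and H3C10 by 1.97 (SE 0.12), and with the offsets they were at -2.32 and -1.29. The offset of H2BC15 rests on an annotated transcript of 4137 bases with 39.5% GC. Where the longest transcript is not the main one, the offsets may correct a gene wrongly. Of 14 listed small structured RNAs 6 were tested, and all 6 were lower (median -2.22, camera adjusted p = 0.00222, and adjusted p = 0.449 with an estimated correlation), SNORD3B-1 among them (-2.41, SE 0.19). They do not stand for small RNAs as a class. Of 213 small nuclear RNA genes tested, 133 were higher and 29 lower (median 1.08). Small nucleolar RNA genes gave 55 higher and 29 lower of 142 (median 0.38). S-phase genes gave 10 higher and 21 lower of 40 (median -0.42, camera adjusted p = 0.0360, and adjusted p = 0.347 with an estimated correlation), with MCM2 and MCM5 lower (-1.56 and -1.65, and -0.58 and -0.73 with the offsets). The call did not hold with the offsets (6 higher, 20 lower, median -0.19, camera adjusted p = 0.0927), with the replicate number as a block (adjusted p = 0.055), without ERRg replicate 3 (adjusted p = 0.0615), with upper-quartile factors (adjusted p = 0.171), with library totals (adjusted p = 0.325), with the stricter low-count filter (adjusted p = 0.162) or with coding genes alone (adjusted p = 0.926). G2 and M-phase genes gave 18 higher and 24 lower of 51 (median -0.13, camera adjusted p = 0.0846), and with the offsets 8 higher and 28 lower (median -0.15, camera adjusted p = 0.0927). UBE2C (-1.49 and -0.49) and CKS1B (-1.31 and -0.87) were lower in both fits.

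Stress-response lists were mostly lower with TMM alone. Endoplasmic reticulum chaperone and unfolded-protein genes were lower in 12 of 16 (median -0.73, camera adjusted p = 0.00150, and adjusted p = 0.347 with an estimated correlation), and in 11 of 16 with the offsets (median -0.23, camera adjusted p = 0.0477, and adjusted p = 0.611 with an estimated correlation). That list was not called with coding genes alone (camera adjusted p = 0.1102). XBP1 fell from 130.5 ± 9.97 to 52.3 ± 4.93 CPM. Integrated stress response genes were lower in 15 of 19 (median -1.06, camera adjusted p = 1.42e-04, and adjusted p = 0.347 with an estimated correlation), with the serine synthesis enzyme PHGDH at -1.73 and ATF5 at -1.43. With the offsets PHGDH was lower by 1.21, and ATF5 did not pass the test (-0.044, adjusted p = 0.575). The p53 targets were lower in 16 of 25 (median -0.59, camera adjusted p = 0.00610, and adjusted p = 0.347 with an estimated correlation), antioxidant genes in 15 of 20 (median -0.94, camera adjusted p = 0.00222, and adjusted p = 0.347) and immediate early genes in 13 of 15 (median -1.02, camera adjusted p = 0.00222, and adjusted p = 0.347). With the offsets 6 integrated stress genes were higher and 10 lower, 8 p53 targets higher and 9 lower, 6 antioxidant genes higher and 6 lower, and 5 immediate early genes higher and 3 lower. None of these 4 lists was then called (camera adjusted p = 0.398, 0.5996, 0.915 and 0.752). HMOX1, which degrades haem, fell by 1.57 (SE 0.10), and by 0.39 with the offsets. Heat-shock genes (3 higher, 6 lower of 11, median -0.70, camera adjusted p = 0.244) and hypoxia genes (6 higher, 9 lower of 18, median -0.11, camera adjusted p = 0.309) were not called, nor with the offsets (3 higher and 6 lower, camera adjusted p = 0.752, and 5 higher and 5 lower, camera adjusted p = 0.578). Interferon-stimulated genes gave 6 higher and 12 lower of 29, with a median of 0.01, a mean of -0.38 and a camera adjusted p = 0.422, and with the offsets 6 higher and 6 lower (camera adjusted p = 0.897).

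Glycolysis genes were lower in 17 of 17 (median -0.99, camera adjusted p = 4.20e-06, and adjusted p = 0.449 with an estimated correlation), among them the neuronal enolase ENO2 (109 ± 15.6 to 33.5 ± 4.93 CPM) and PFKL (log2 fold change -1.69). With the offsets ENO2 fell by 0.75 and PFKL by 0.53 on the log2 scale. Lysosomal genes were lower in 19 of 27 (median -0.72, camera adjusted p = 2.27e-04, and adjusted p = 0.451 with an estimated correlation) and cholesterol synthesis and uptake genes in 14 of 23 (median -0.78, camera adjusted p = 0.00731, and adjusted p = 0.347 with an estimated correlation). With the offsets 12 of 17 glycolysis, 14 of 27 lysosomal and 13 of 23 cholesterol genes were lower, and none of these 3 lists was called (camera adjusted p = 0.1198, 0.510 and 0.478). Genes linked to inherited Parkinson disease gave 6 higher and 8 lower of 15 (median -0.77, camera adjusted p = 0.407), and with the offsets 5 higher and 6 lower (camera adjusted p = 0.682). Biotin-dependent enzymes and biotin handling genes gave 2 higher and 5 lower of 10 (median -0.19, camera adjusted p = 0.407), and with the offsets 3 higher and 4 lower (camera adjusted p = 0.915).

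Markers of other cell types were mostly lower in ERRg, and several were expressed in both groups. Of 12 leukocyte markers 2 were tested, CSF1R at 1.57 ± 0.142 CPM in ERRg and 2.10 ± 0.0606 CPM in GFP and FCER1G at 0.435 ± 0.218 and 0.432 ± 0.174 CPM (camera adjusted p = 0.886). Both were higher with the offsets (camera adjusted p = 0.682). Of 6 glial markers 1 was higher and 4 lower (median -0.83, camera adjusted p = 0.453), and of 4 endothelial markers 1 was higher and 2 lower (median -0.36, camera adjusted p = 0.440). MBP was at 6.86 ± 0.381 CPM in ERRg and 13.5 ± 1.60 CPM in GFP, and EGFL7 at 4.66 ± 0.666 and 20.4 ± 2.96 CPM (log2 fold change -2.13, and -0.69 with the offsets). With the offsets 2 glial markers were higher and 1 lower (camera adjusted p = 0.915), and 2 endothelial markers higher and 1 lower (camera adjusted p = 0.823). Of 7 epithelial markers 5 were lower and 0 higher (median -0.9987, camera adjusted p = 0.0437, and adjusted p = 0.463 with an estimated correlation), with CLDN4 at 7.32 ± 1.24 CPM in ERRg and 35.2 ± 4.02 CPM in GFP and KRT8 at 17.0 ± 1.87 and 34.0 ± 2.88 CPM. That call ended with the offsets (3 higher, 2 lower, camera adjusted p = 0.915), with CLDN4 at -1.36 and KRT8 at -0.19 against -2.27 and -0.9987 with TMM alone.

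**Figure D5:**
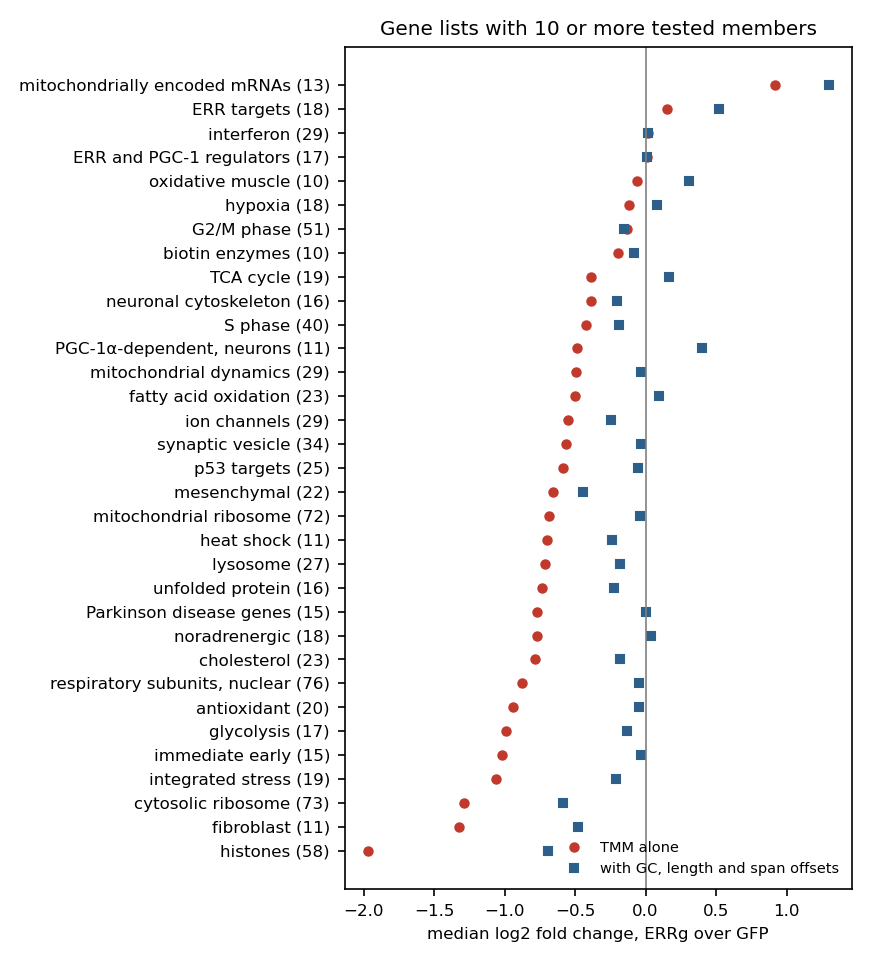
Median log2 fold change (ERRg over GFP) of each list with 10 or more tested members, with TMM alone (circles) and with offsets for GC content, length and span (squares), with the number of tested genes in parentheses. Histones (-1.97 and -0.69) and mitochondrially encoded mRNAs (0.92 and 1.30) stand at the ends of the range in both.

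Adjusted over the list alone, the counts of called members were the same as over all genes in 34 of the 38 lists. The other 4 were the receptor targets (8 higher, 8 lower), interferon genes (5 higher, 11 lower), histones (57 lower) and leukocyte markers (0 lower). Camera with the preset correlation called 1 list higher and 19 lower, and none of these calls held with an estimated correlation, for which the lowest adjusted p was 0.347.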

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

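The tests of genomic DNA, of intronic genes and of the respiratory genes were chosen only after the results they bear on were seen. The offsets and the covariate were also added then. The bootstrap intervals below resample genes, so they do not measure the spread between libraries.

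Within-group gaps were tested by Dixon's criterion in 228 groups of 4 libraries, of which chance alone is expected to mark about 5%, and 17 were marked. GFP replicate 2 accounted for 11 of them, each time as the highest library. Its CPM was 37.2 for RTL1 (24.7 to 26.6 in the other GFP libraries), 56.2 for COX8A, 43.7 for PPARD, 77.4 for MRPS26, 1497 for RPS14, 504 for RPS12, 59.1 for IFITM3, 67.0 for JUND, 132 for ENO2, 151 for TM7SF2 and 2.45 for ZFYVE28 (1.40 to 1.48 in the others). ERRg replicate 1 was lowest for PTGER1 (0.165 CPM) and MBP (6.30 CPM), and ERRg replicate 3 was highest for ROBO4 (0.944 CPM). ERRg replicate 2 had the most reads of its group (55.5 M) and the most genes with a count (33922), and GFP replicate 1 had the most genes with a count of its group (33485).

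GFP replicate 2 also had the lowest share of reads outside annotated exons, 16.2%. Against the mean of the other 3 GFP libraries, its log2 CPM rose by 0.148 per 10 GC points across coding genes, and the slopes of the other GFP libraries lay between -0.09 and -0.03. Within ERRg the slopes were -0.19 and -0.15 in replicates 1 and 2, and 0.22 and 0.11 in replicates 3 and 4. The slope of ERRg replicate 3 was thus larger than that of GFP replicate 2. A library effect that follows GC content, in the direction of the difference between the groups but smaller, may therefore set GFP replicate 2 apart. No biological explanation was tested for it, because the labels give no difference among replicates.

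The first pattern weighed is the number of calls, 74.7% of tested genes, with GC-rich genes lower in ERRg. Genomic DNA was weighed as the whole source of the additional reads outside exons. Of 515 receptor, keratin-associated and defensin genes, 9.13% to 11.5% had a count in the ERRg libraries. Even spreading of the additional reads over the genome predicts 88.5% to 91.1% (highest ratio of the shares 0.127), which argues against it. In the GFP libraries the share was 6.02% to 7.57%, below each ERRg library, so a smaller part from genomic DNA stays open. More unspliced RNA stays open too. Here, 198 genes inside introns lay 0.61 above coding genes of the same GC content, length and level (95% bootstrap interval 0.50 to 0.71). GC-dependent recovery also stays open, since 314 coding genes with a single exon showed a slope of -0.78 per 10 GC points (95% bootstrap interval -0.91 to -0.64), against -0.65 in multi-exon genes. An effect of ERRg itself stays open and untested, because the share of reads outside exons goes with group.

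The second pattern is the opposite movement of mitochondrially encoded and nuclear respiratory mRNAs. For the mitochondrial part, the median was 1.30 with the offsets over GC content, length and span. These genes have spans as short as their transcripts (207 bases for MT-ATP8 and 525 for MT-ND6). Nuclear coding genes with a single exon were few (314, against 12192 with more), so the fitted trend may not hold for the mitochondrial ones. The median of 1.30 therefore does not decide whether the trend plays a part. The call of this list ended with the offset for GC content alone (median 0.97, camera adjusted p = 0.0859). It also ended with the offsets and an estimated correlation (camera adjusted p = 0.611). With the share of reads outside annotated exons as a covariate the median was -0.0083. Loss of cytoplasm together with its mitochondria predicts a mitochondrial median no higher than that of coding genes. The measured median lay 1.21 above it, with 12 of the 13 mRNAs above it. These values are the pattern itself and were known beforehand, so they are no separate test of this explanation. A loss of cytosol that keeps mitochondria stays open. For the nuclear part, the trend of all other coding genes predicted a median of -0.48 where -0.88 was measured, and the median deviation per subunit was -0.05 (95% bootstrap interval -0.17 to 0.07). How much of the nuclear fall is that trend cannot be told apart from an effect of ERRg, because the predicted median explains a part of it and the members go both ways once the trend is removed.

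As to chance, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave 16428 called genes. The highest of the other splits gave 0. Each of these mixes the groups and carries the group difference as spread within its own groups, so few calls were likely in any case. The splits therefore cannot exclude a chance difference in culture or handling shared by the libraries of a group. For the number of lists called by camera, 9 of the 35 splits gave as many as the real 20, and the highest of the others gave 23, so this count does not exclude chance. Each of the other 8 exchanged 1 library between the groups and so holds part of the real difference, and the 18 splits with 2 libraries of each group on either side gave at most 7 lists.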

How the results depend on the processing

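Library totals, equal depth, the offsets and the covariate were chosen only after the data were seen. The cause of each change below was not tested, except where the alternative tests fewer genes or a stricter threshold.

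ESRRG, SPP1 and ZFYVE28 kept their direction and their call under each alternative that tested them. With coding genes alone, 5474 genes were higher and 8 lists lower, and the lists of neuronal cytoskeleton, noradrenergic, S-phase, p53, unfolded-protein, immediate early, cholesterol, lysosome, antioxidant and epithelial genes lost their calls. Against a log2 fold change of 1, 1692 genes were higher and 2302 lower. Of the lists, 0 were called higher with the DESeq2 Wald test and 0 without mitochondrially encoded genes, which leaves out the list that was higher. An estimated correlation gave 0 higher and 0 lower, with and without the offsets, and fry, which does not compare a list with other genes, gave 34 lower. Without mitochondrially encoded genes in the denominator, the difference in the share of the 10 most abundant genes turned from 1.21 to -0.535 points.

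With the GC offset, 4850 genes were higher and 4863 lower, and 1 list higher, the receptor targets (median 0.40), and 9 lower. Log2 fold changes that turned were ESRRA 0.78, PPARGC1B 0.035, IDH3G 0.16, PPRC1 0.048, PPARD 0.15, PC 0.12 and CSF1R 0.58. With offsets for GC content, length and span, 4652 genes were higher and 4861 lower, and 2 lists higher and 5 lower. Those that turned were ESRRA 0.85, IDH3G 0.35, HSD17B10 0.030, ECHS1 0.083, PPRC1 0.024 and CSF1R 0.41. By the direction of the set test 13 lists turned, 3 of them called with TMM alone or with the offsets: immediate early genes (median -0.035), antioxidant genes (-0.047) and epithelial markers (0.10), with either correlation. The other 10 were called in neither, and some medians kept their sign.

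With the share of reads outside annotated exons as a covariate, 6 genes were higher and 2 lower, and 4 lists higher and 3 lower. This share correlates with group at 0.984, so the directions in this fit are poorly determined. AC006042.3 turned from 1.40 to -5.21 and BX005019.1 from 0.54, not called, to -5.43. Genes named by the rule that turned, none of them called with the covariate, were ESRRA 0.99, PPARGC1A -0.030, UQCRQ 0.00699, IDH3G 0.12, ATP5F1A 0.25, TNNT1 0.18, CKMT2 -0.69, STAT2 0.19, PMVK 0.13, gene ATP6V0D1 0.000224, CHCHD2 0.034, PC 0.23 and ROBO4 1.14. Lists called with TMM alone or with the covariate that turned had medians of 0.20 (nuclear respiratory subunits), 0.16 (tricarboxylic acid cycle) and 0.22 (fatty acid oxidation), these 3 called higher, and -0.11 (noradrenergic), -0.45 (immediate early), 0.019 (glycolysis), 0.034 (cholesterol), -0.010 (list lysosome), -0.12 (antioxidant) and -0.45 (structured RNAs).

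With each library left out in turn, between 7611 and 8518 genes were higher and between 7755 and 8247 lower. CSF1R did not pass the test without any 1 of the ERRg libraries. The S-phase list lost its call without ERRg replicate 3, and the epithelial list without GFP replicate 1 or 2. The G2 and M-phase list gained one without GFP replicate 1, 2 or 3 or ERRg replicate 1. With the replicate number as a block, 8191 genes were higher and 7653 lower, and gene CSF1R (edgeR adjusted p = 0.0855) and the S-phase list (camera adjusted p = 0.055) lost their calls. Depth limits genes such as PPARGC1A, with 3 to 14 reads per GFP library, and ESRRB, with at most 9 reads in any library.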

Other observations

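The strand test of the chromosome 11 block was chosen after the block had been seen, and its outcome had not been seen when it was written. The genes in this part were named after their values were seen.

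Genes of the globin and olfactory receptor cluster on chromosome 11 were higher in ERRg. Of 20 tested genes and pseudogenes from 5253190 to 5678434 on GRCh38, 19 were higher (median log2 fold change 2.20, range 0.73 to 3.40). OR51M1 rose from 2.86 to 17.4 CPM, OR51I2 from 2.96 to 13.9 CPM and OR51B5 from 3.21 to 9.61 CPM. The gene annotated as the embryonic globin HBE1 had a log2 fold change of 2.44 (SE 0.48, edgeR adjusted p = 1.26e-04) at 0.0739 CPM in GFP and 0.421 CPM in ERRg, while HBG2 did not pass the test (0.79, SE 0.36, edgeR adjusted p = 0.0504). As annotated, HBE1 runs from 5268345 to 5505652 and HBG2 from 5253190 to 5505605. Both overlap OR51B5 on the same strand, so their reads need not come from globin transcripts. The 15 tested genes that start within 1 megabase on either side had a median of -0.65, and 3 of them were higher. With the offsets all 12 coding genes of the block were higher (median 2.58, range 1.07 to 3.17). Among 13206 windows of 10 neighbouring coding genes, the largest absolute median with the offsets was 2.68, in this block, and the largest outside it was 1.43, on chromosome 6.

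One hypothesis was that a single transcript runs along the block. It requires the higher genes to lie on one strand, and 11 of the 19 lay on the strand of OR51B5 and the others on the opposite strand (exact two-sided binomial p = 0.648), which argues against a single transcript as the whole source. Some of the 11 overlap as annotated, HBE1 and OR51B5 among them, so they are not independent in the binomial test.

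On chromosome 14, 3 coding genes picked around the imprinted DLK1 locus were lower, as were 6793 of all 13433 coding genes. Other genes of this neighbourhood were not counted, so the 3 do not show an effect on the locus. BEGAIN had a log2 fold change of -2.14 (SE 0.15), DLK1 of -2.70 (SE 0.21) and RTL1 of -4.73 (SE 0.19), and with the offsets these were -1.07, -1.78 and -3.73.

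By gene type, 308 of 458 genes annotated inside introns were higher and 17 lower (median 0.93), 1164 of 1672 processed pseudogenes were higher and 105 lower (median 1.05), and 3890 of 13433 coding genes were higher and 6793 lower (median -0.30).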
